A study of Homo sapiens with 24 samples.

How the data were processed

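RNA from 24 cultures of LNCaP cells with a doxycycline-inducible MYC construct was measured on Illumina bead arrays with 47323 probes, in 8 groups of 3 (vehicle, R1881, Dox, and R1881 with Dox, at 5 h and 12 h), grouped per the labels. The signal intensity of each probe was deposited on a linear scale as exported by GenomeStudio 2011.1, per the submitters' processing notes, and the values show no background subtraction or normalization, with array minima at or above 65.4 and array medians of 86.87 to 102.1. The detection p-value of each probe on each array was deposited beside the intensity, per the file headers. A second deposited table holds intensity values that the authors normalized between arrays, and its column medians of 95.8 and 90th percentiles of 351, alike on the 24 arrays to 3 digits, point to quantile normalization, an inference from the values. Each array's ranks in that table correlated best with its own column of the first table. No genome build is stated for the probes in the sources used here, so no positions are given.

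The deposited intensity was corrected for background and quantile normalized with the neqc function of limma 3.58.1 in R 4.3.3, with an offset of 16 and negative control intensities inferred from the detection p-values, and taken to log2. Gene symbols came from the platform's annotation: 30113 probes had 1 symbol, 8 had several and 17202 had none, and 30074 were matched by gene number to the reference gene table for GRCh38.p14, from which the symbol was updated. A probe was kept where its detection p was under 0.01 on all 3 arrays of at least 1 group, which left 14442 probes, of which 11596 had 1 symbol. The brightest kept probe over the 24 arrays stood for a gene, and 9113 genes were tested, of which 2039 had more than 1 kept probe. Between 13081 and 14980 probes were detected per array. For arrays, their number limits the precision, and with 3 arrays per group an exact permutation test of 1 value cannot give a two-sided p under 0.1.

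A linear model with a mean for each of the 8 groups was fitted to all arrays with limma (16 residual degrees of freedom), with empirical Bayes variances and Benjamini-Hochberg adjustment over the 9113 genes within each of 12 contrasts. The contrasts were R1881 against vehicle, Dox against vehicle, both treatments against each one alone, the interaction, each at 5 h and 12 h, and the difference between the times for R1881 and for Dox. A gene was called at an adjusted p under 0.05. The groups were checked for pairing by replicate number through residual correlations: the residuals of all 3 pairs correlated above 0.1 for Dox against vehicle at both times and for both treatments against each one alone at 12 h, and 23 of 24 arrays correlated best with arrays of their own number. The replicate number was not part of the model chosen before the data were examined, so a blocked count stands beside the other where the numbers pair the groups and the block moved the count by over 1.5 times. The rest of the blocked counts are given with the other alternatives.

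Gene lists written before the data were examined (24 lists, 23 with measured members) were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, each adjusted over the lists. List members were also counted at an adjusted p over all genes and adjusted over the list alone. The share of the androgen response kept with Dox was computed over genes called at one time and measured on the arrays of the other time, each gene signed by its change, with the SE from the spread of the array means and a fry test of the interaction, adjusted over both directions. Where a probe was not above background on any array of a group, the fold is a lower bound against the level at which detection begins. This bound is on the background-corrected scale, depends on that correction and leaves out the SE.

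Genes were named by a rule set before the data were examined: per comparison, called genes whose replicates do not overlap between groups, up to 8 rises and 8 falls of largest size at 12 h and 4 of each at 5 h, up to 4 called members of each list with at least 3 such members, and a fixed set with MYC, KLK3, KLK2, TMPRSS2, FKBP5, ODC1, NCL, CAD and CDKN1A. The other two genes of the fixed set had no probe under their symbols in the annotation used and are not analysed here.

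The fit was tested on simulated data with the real means and variances and with noise drawn independently for each gene and array. Such noise lacks the correlation of arrays by replicate number described above, so recovery in the real data may differ. Of 67 genes changed by 0.5 log2 units in R1881 against vehicle at 12 h, 46.3% were recovered, of 67 changed by 1 unit 92.5%, and of 66 changed by 2 units 100%. For the interaction at 12 h the shares were 19.4%, 71.6% and 98.5%. Of 8382 unchanged genes, 6 were called in the former and 4 in the latter. A simulated share kept of 80% was recovered as 78.2%. A simulated shift of the androgen-induced list by 0.3 log2 units passed the list test, but its mean was recovered as 0.41, larger than set.

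The alternatives tried were no background correction, 75th-percentile scaling, the authors' normalized values, no detection filter, detection on all 24 arrays, the mean of a gene's kept probes, the replicate number as a block, a fit to the compared groups alone, an eBayes trend with robust priors, array weights, a fold of at least 1.5, a stricter gene choice for the share kept, and leaving out each array in turn. An array order block was added after the data were seen. The slide of each array is not given in the sources used here, so a slide block was not run. Probes with no gene symbol or several were left out of the gene counts, and 2846 of them that passed the detection filter were tested on their own.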

Results

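LNCaP cells, a line from a human prostate cancer metastasis that grows in response to androgen, carried a MYC construct that doxycycline (Dox) switches on, per the labels. Cells kept in charcoal-stripped serum, which holds little hormone, received vehicle (EtOH), the synthetic androgen R1881 at 1 nM, Dox at 2 ug/mL, or both, for 5 h or 12 h. Expression was measured on 24 Illumina bead arrays in 8 groups of 3, which the labels call biological replicates. The design asks how cells respond to androgen, to Dox with the MYC construct, and whether Dox changes the androgen response. Between 13081 and 14980 probes were detected per array, and arrays of a group correlated at 0.979 to 0.994 across probes. Tests covered 9113 genes, with a median SE of 0.139 log2 units for a difference between 2 groups, and the number of arrays limits the precision. Errors are the SE from limma with n = 3 arrays per group, and a gene is said to rise or fall where limma's adjusted p was under 0.05. For each such value of a gene named for a comparison of 2 groups, the 3 arrays of one group all lay above those of the other. Chance gives this for 10% of genes, but it was a condition for naming the largest rises and falls, so it is no separate support. Without background correction, 59 of the 161 called values of named genes were smaller by over 1.5 times. No group had Dox without the construct, so effects of the drug and of MYC cannot be separated in any Dox comparison.

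The MYC probe, ILMN_1680618, had a mean log2 intensity of 10.81 with vehicle, 10.38 with Dox, 10.33 with R1881 and 9.90 with both at 12 h. The place of this probe relative to the construct is not known here, so its signal does not check the induction. With R1881 at 12 h, MYC fell by 0.48 ± 0.14 log2 units (adjusted p = 0.0303). Its call was lost in 5 of 17 alternatives, without the detection filter and without vehicle replicate 1 or 2 or R1881 replicate 2 or 3, with values from −0.48 to −0.42 on leaving these out. The change with Dox was −0.43 ± 0.14 in cells without androgen (adjusted p = 0.113) and −0.42 ± 0.14 in cells with it (adjusted p = 0.0797), and neither passed the test. With the replicate number as a block, both passed (adjusted p = 0.0183 and 0.0133), as they did with array weights (adjusted p = 0.0347 and 0.0404). The change in cells with androgen also passed with a variance trend and without replicate 1 of both treatments (−0.55). For both treatments against Dox alone the change was −0.48 (adjusted p = 0.0515), and it passed in 9 of 17 alternatives. At 5 h the group means of MYC were 10.67 with vehicle, 10.47 with Dox, 10.40 with R1881 and 10.22 with both, and no difference passed. A second MYC probe lay near background, at 4.45 to 5.73.

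**Figure D1:**
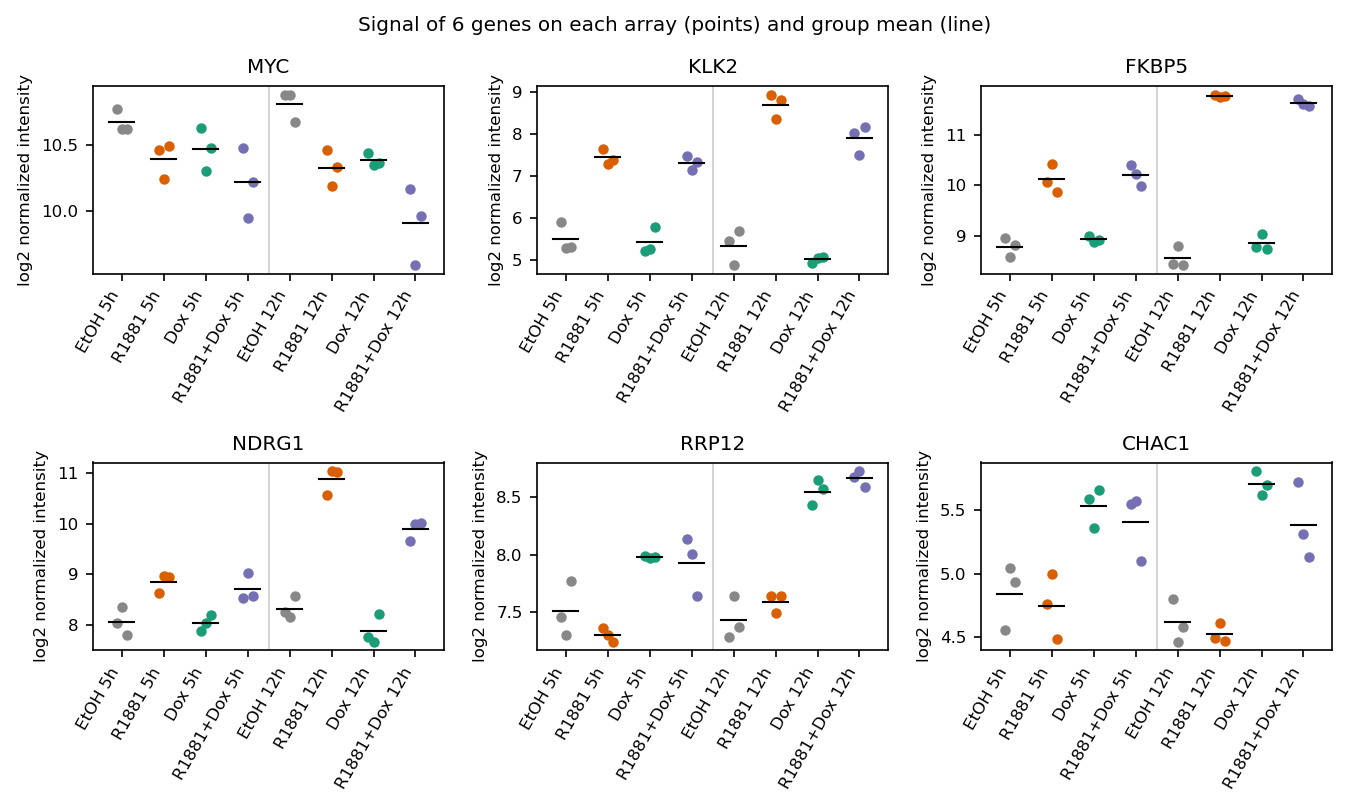
Log2 normalized intensity of 6 genes on each of the 24 arrays (points) with the mean of the 3 arrays of a group (line), by treatment and hours. KLK2, FKBP5 and NDRG1 were higher in the R1881 groups at 12 h, RRP12 and CHAC1 in the Dox groups, and the MYC probe averaged 10.81 with vehicle and 9.90 with both treatments at 12 h.

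Androgen raised the classical androgen receptor targets at both times. At 12 h, KLK2, which encodes a secreted prostate protease, rose by 3.34 ± 0.22 log2 units, FKBP5, a receptor co-chaperone, by 3.23 ± 0.14, TMPRSS2, a membrane protease, by 2.80 ± 0.25, and KLK3, which encodes prostate-specific antigen, by 2.13 ± 0.21 (adjusted p from 8.56e-13 to 2.26e-07). At 5 h KLK2, FKBP5 and TMPRSS2 had risen by 1.94 ± 0.22, 1.34 ± 0.14 and 2.04 ± 0.25. With vehicle at 12 h KLK2 was above background on 2 of 3 arrays, and its 12 h rise was as low as 2.07 across the alternatives, so its size is uncertain. KLK2 and KLK3 are close relatives, and whether their probes tell them apart was not tested, so these values are uncertain as to the gene. SGK1, a kinase induced by steroids, was not above background without androgen and was at least 10.5-fold higher at 12 h and at least 5.21-fold higher at 5 h. These bounds and those below hold for the background-corrected values and leave out the SE. Across the alternatives the SGK1 change at 12 h was as low as 2.20 log2 units, under the 3.39 of its bound. The glucose transporter gene SLC2A3 was at least 4.2-fold and the plasma protein gene ORM1 at least 4.87-fold higher at 12 h. TRIM49D1 and TRIM49D2 were at least 6.54-fold and 5.11-fold higher, but these and TRIM51 are related genes, as are ORM1 and ORM2. Whether their probes tell such relatives apart was not tested, so the gene behind each signal is uncertain.

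The response widened between the times. At 5 h, R1881 changed 157 genes, 126 up and 31 down, and at 12 h it changed 845, 540 up and 305 down. All but 10 of the 126 genes up at 5 h were also called up at 12 h, where independent lists would share 7.47, and of those down at 5 h, 25 were also down at 12 h. These lists compare different arrays but share the variances of the joint fit. When limma was fitted to the 6 arrays of the 5 h comparison alone, 43 genes passed, and leaving out vehicle replicate 3 gave 102. PRAG1, a pseudokinase gene, rose by 2.06 ± 0.12 at 5 h and by 2.29 ± 0.12 at 12 h (1.27 and 1.80 on its other probe), and GRHL2, an epithelial transcription factor gene, by 1.54 ± 0.14 and 1.62 ± 0.14. Genes down at 5 h included LTN1, a ribosome quality control ligase gene (by 0.82 ± 0.12 at 5 h and 1.71 ± 0.12 lower at 12 h), and HOXC13, a homeobox gene. The latter fell by 0.81 ± 0.14 at 5 h and by 1.16 ± 0.14 at 12 h. Among the steepest falls at 12 h were those of the membrane protein genes LRRN1 (fell by 2.25 ± 0.19) and TMEM140 (fell by 2.20 ± 0.23), of IL1RN, which encodes an interleukin antagonist (fell by 2.09 ± 0.22), of PKIB, which encodes a kinase inhibitor (fell by 1.78 ± 0.21), and of the chemokine receptor gene ACKR3 (fell by 1.75 ± 0.26). IL1RN was above background on 1 of 3 arrays with R1881, so the size of its fall is uncertain. CCDC83, a coiled-coil protein gene, was not above background with R1881 and was at least 1.93-fold lower than with vehicle.

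Fixed gene lists placed these genes in pathways. Of 29 measured androgen-induced genes, 20 rose at 5 h (24 adjusted over the list alone) and 28 at 12 h, with mean changes of 1.04 and 1.92 log2 units and adjusted p of 4.68e-08 and 6.05e-08 with an estimated correlation. Of 15 androgen-repressed genes, 5 fell and 1 rose at 12 h (8 and 1 adjusted over the list alone), with a mean of −0.708 and an adjusted p of 2.32e-05, or 0.056 with an estimated correlation. In that list CAMK2N1, a kinase inhibitor gene, fell by 1.02 ± 0.13, while UGT2B28, an androgen-conjugating enzyme gene, rose by 1.27 ± 0.31, a call lost without vehicle replicate 1 (1.09) or R1881 replicate 3 (1.12). The unfolded protein response list had 10 of 17 members up at 12 h (14 adjusted over the list alone) and a mean of 0.581, with an adjusted p of 0.0126 with an estimated correlation. Its chaperone genes DNAJB9, MANF and HSPA5 rose by 1.49 ± 0.24, 1.08 ± 0.12 and 1.03 ± 0.17, and none of them had changed at 5 h by limma's test. The secretory pathway list had 7 of 13 members up (11 adjusted over the list alone), with a mean of 0.480 and an adjusted p of 9.66e-05 with an estimated correlation, among them CREB3L2, a secretory transcription factor gene, at 0.87 ± 0.12, and TMED9, a cargo receptor gene, at 0.61 ± 0.10. Of 20 cholesterol and fatty acid synthesis genes, 6 rose at 12 h, with the sterol sensor gene SCAP at 0.64 ± 0.11 and its partner INSIG1 at 0.46 ± 0.12 (list mean 0.212, adjusted p = 0.013 with an estimated correlation). INSIG1 lost its call without vehicle replicate 1 (0.43) or R1881 replicate 1 (0.41).

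Some polyamine and lineage genes moved at 12 h, though their lists did not pass the camera test. The nucleotide, polyamine and one-carbon list had 3 of 24 members up and a mean of 0.019 (adjusted p = 0.946). The prostate lineage list had 2 up and 2 down of 7 (mean 0.347, adjusted p = 0.412, or 2.75e-05 by fry), and the integrated stress response list 1 up and 1 down of 17 (mean −0.153, adjusted p = 0.302). ODC1 and SMS, which encode enzymes of polyamine synthesis, rose by 0.82 ± 0.12 and 0.87 ± 0.10. SPDEF, a prostate luminal transcription factor gene, rose by 1.97 ± 0.12 (adjusted p = 3.30e-10). HOXB13, a prostate homeobox gene, fell by 0.30 ± 0.09 (adjusted p = 0.0397). Its call was lost with 75th-percentile scaling, in the fit to the 6 arrays alone and on leaving out any array but vehicle replicate 3 (from −0.31 to −0.25). NDRG1, a stress- and androgen-responsive gene, rose by 2.55 ± 0.18 and belongs to the androgen-induced, growth-arrest and hypoxia lists. The growth regulator genes KLF6 and GADD45B rose by 0.92 ± 0.16 and 0.65 ± 0.13, after 1.18 ± 0.16 and 0.68 ± 0.13 at 5 h. GADD45B lost its 5 h call with array weights and in the fit to the 6 arrays alone. The growth-arrest list had 4 members up and 1 down of 13 at 5 h, with a mean of 0.183 and an adjusted p of 0.0441, or 0.255 with an estimated correlation. At 12 h it had 5 up and 0 down (5 up and 3 down adjusted over the list alone), with a mean of 0.302 and a median of −0.031. It did not pass at 12 h by camera (adjusted p = 0.14, or 0.268 with an estimated correlation), and had an adjusted p of 1.67e-04 by fry. The 7 hypoxia-inducible genes measured had 4 members up at 12 h and a mean of 0.701, with an adjusted p of 0.00121, or 0.0625 with an estimated correlation. Ribosome biogenesis genes had a mean of −0.115 at 5 h, with 0 of 32 past limma's adjusted test for single genes and an adjusted list p of 0.00527, or 0.671 with an estimated correlation. NCL, a nucleolar protein gene, CAD, a pyrimidine synthesis enzyme gene, and CDKN1A, a cell cycle inhibitor gene, had changes of −0.18 ± 0.20, 0.01 ± 0.15 and −0.31 ± 0.21 at 12 h, none past the test.

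Dox without androgen raised ribosome, nucleotide and amino acid stress genes. At 12 h, RRP12, a ribosomal subunit export gene, rose by 1.12 ± 0.13 log2 units, MTHFD1L, a mitochondrial folate enzyme gene, by 1.12 ± 0.13, the endothelin-processing enzyme gene ECE2 by 1.31 ± 0.13 (0.83 on its other probe), the signalling ligand gene WNT10B by 1.24 ± 0.19 and the amino acid transporter gene SLC7A2 by 1.11 ± 0.14 (adjusted p from 9.90e-06 to 6.54e-04). CHAC1, a glutathione-degrading enzyme gene of the stress response, was not above background with vehicle and was at least 1.45-fold higher with Dox, in 3 of 3 arrays above background, and the glutamate transporter gene SLC1A3 was at least 1.4-fold higher. At the same time KLK3 fell by 0.93 ± 0.21 (adjusted p = 0.016), the prostate protease gene KLK4 by 0.66 ± 0.11, the prostate transporter gene SLC45A3 by 0.57 ± 0.10, and the membrane protein gene TMEM45B by 0.87 ± 0.16. KLK3 lost its call in 5 of 17 alternatives. These were no background correction (−0.53), the fit to the 6 arrays alone (−0.93), and leaving out vehicle replicate 1 or 2 or Dox replicate 2 (from −0.93 to −0.72). TMPRSS2 and FKBP5 had changes of −0.84 ± 0.25 and 0.31 ± 0.14 with Dox at 12 h, and neither passed (adjusted p = 0.0736 and 0.315). TMPRSS2 passed with the replicate number as a block (adjusted p = 0.00292), with array weights (adjusted p = 0.00956) and in the fit to the 6 arrays alone (adjusted p = 0.022). KLK2 was not above background with Dox, so its change has no size, and it did not pass (adjusted p = 0.575).

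Dox changed 67 genes at 5 h, 65 up and 2 down, and 289 at 12 h, 236 up and 53 down. With the replicate number as a block, which the residuals of these arrays called for, the counts were 121 and 473, and with array weights 38 and 737. Fitted to its 6 arrays alone, the 5 h comparison called 0 genes by limma, with 790 at an unadjusted p under 0.05 in the fit of all arrays, and the 12 h comparison called 156. Without Dox replicate 1 the 5 h count was 11. Of the 65 genes up at 5 h, 49 were also up at 12 h, where independent lists would share 1.68. At 5 h SOX8, a transcription factor gene, rose by 1.36 ± 0.14 (0.56 ± 0.14 at 12 h), STC2, a secreted stress-response gene, by 0.95 ± 0.12 (0.60 ± 0.12 at 12 h), and TWNK, which encodes the mitochondrial DNA helicase, by 0.93 ± 0.13 (0.86 ± 0.13 at 12 h). The 12 h call of SOX8 was lost on leaving out any array but vehicle replicate 2 (0.49 to 0.58), and that of STC2 without vehicle replicate 3 (0.53). The 2 genes down at 5 h were MMAA, a cobalamin pathway gene (fell by 0.58 ± 0.12), and HSD17B11, a steroid dehydrogenase gene (fell by 0.49 ± 0.11). MMAA lost its call in 7 of 16 alternatives and HSD17B11 in 12 of 17, among them no background correction and the authors' normalized values for both. Leaving out vehicle replicate 2 or Dox replicate 1 or 3 ended the call of MMAA, and leaving out any of the 6 arrays that of HSD17B11, each with values from −0.56 to −0.43.

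Of 32 ribosome biogenesis genes, 5 rose at 5 h (14 adjusted over the list alone) and 15 at 12 h (21 adjusted over the list alone), with mean changes of 0.323 and 0.487 and adjusted p of 0.0157 and 0.00232 with an estimated correlation. RRP9, a small nucleolar RNP gene, rose by 0.88 ± 0.14 at 12 h, and BOP1, a large subunit assembly gene, by 0.76 ± 0.11. The nucleotide, polyamine and one-carbon list had 6 of 24 members up at 12 h (13 adjusted over the list alone), with a mean of 0.332 and an adjusted p of 0.0333 with an estimated correlation. CAD rose by 0.66 ± 0.15 and PPAT, a purine synthesis gene, by 0.55 ± 0.11, but both lost their call in the fit to the 6 arrays alone and without vehicle replicate 3 (0.53 and 0.45) or Dox replicate 2 (0.59 and 0.49). ODC1, NCL and CDKN1A had changes of 0.20 ± 0.12, 0.29 ± 0.20 and −0.06 ± 0.21 with Dox, none past the test. The mitochondrial import and translation list had 5 of 20 members up and a mean of 0.238 (adjusted p = 0.00232 with an estimated correlation), with the import chaperone gene TIMM10 at 0.67 ± 0.11, a call lost in the fit to the 6 arrays alone. The integrated stress response list, which follows amino acid shortage and related stresses, had 8 of 17 members up at 12 h (12 adjusted over the list alone), with a mean of 0.502 and an adjusted p of 0.00232 with an estimated correlation. Its members TRIB3, a pseudokinase gene, and CEBPB, a transcription factor gene, rose by 0.84 ± 0.12 and 0.76 ± 0.13. At 5 h that list had a mean of 0.243 with 1 member up (4 adjusted over the list alone) and an adjusted p of 5.15e-05, or 0.145 with an estimated correlation.

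Further lists went either way with Dox at 12 h, with means from −0.229 to 0.230. Androgen-induced genes had a mean of −0.219 at 12 h, with 5 of 29 down (6 adjusted over the list alone) and an adjusted p of 0.0358 with an estimated correlation. Growth-arrest genes had a mean of −0.220 with 0 of 13 past limma's adjusted test for single genes (list adjusted p = 0.0358 with an estimated correlation), and prostate lineage transcription factors a mean of −0.229 with 1 of 7 down (0.0358 with an estimated correlation). The androgen-repressed list had a mean of −0.225 and 0 members past the test by limma, with an adjusted p of 0.0474, or 0.357 with an estimated correlation. G1/S and DNA replication genes had a mean of 0.230 with 1 of 25 up (2 adjusted over the list alone) and an adjusted p of 1.99e-04, or 0.357 with an estimated correlation. Translation factor genes had a mean of 0.162 with 1 of 14 up and an adjusted p of 0.0314, or 0.0517 with an estimated correlation. At 5 h androgen-induced genes had a mean of −0.087, nucleotide synthesis genes 0.165, mitochondrial import and translation genes 0.111 and G2/M genes −0.129, and each of these calls was lost with an estimated correlation (adjusted p = 0.283, 0.283, 0.280 and 0.759).

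**Figure D2:**
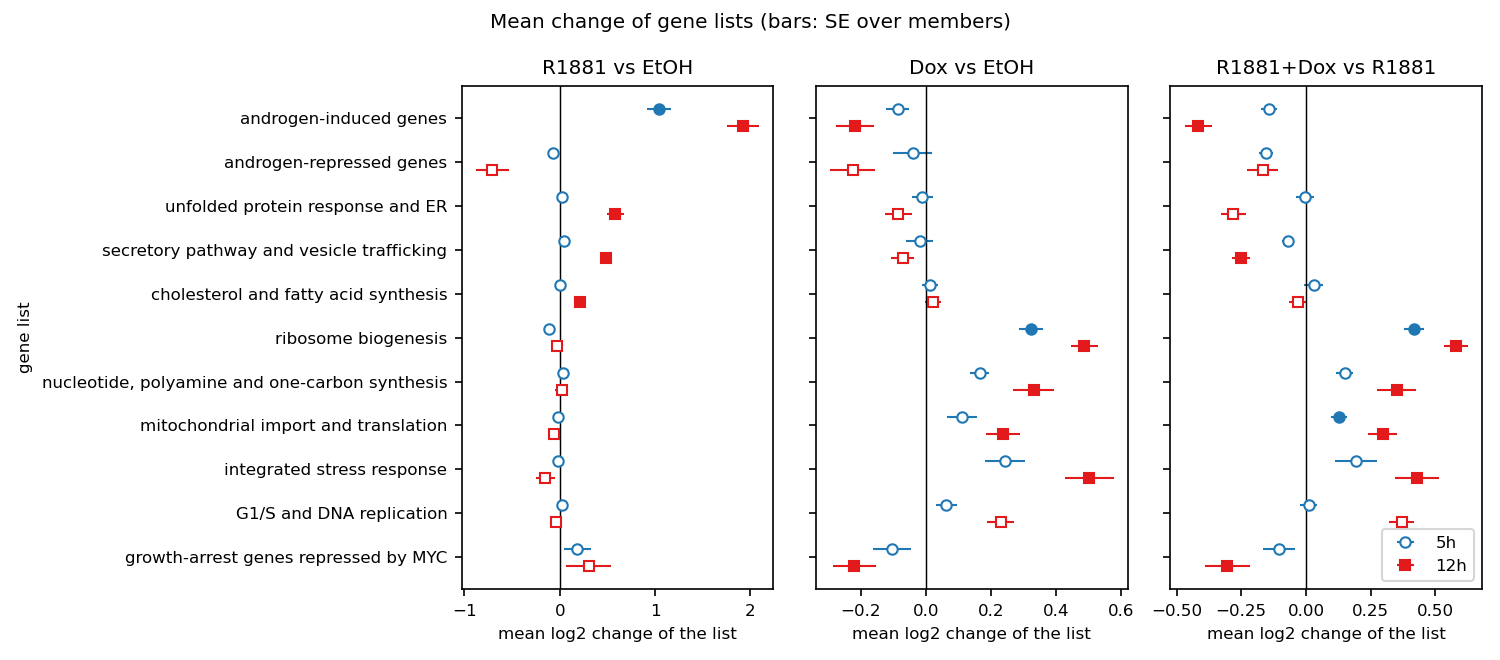
Mean log2 change of 11 gene lists in 3 comparisons at 5 h (circles) and 12 h (squares), with bars for the SE over the list's members and filled symbols where the adjusted p with an estimated correlation was under 0.05. Androgen-induced genes reached a mean of 1.92 with R1881 at 12 h, and ribosome biogenesis genes 0.487 and 0.579 with Dox at 12 h without and with R1881.

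In cells that had androgen, Dox raised genes that it also raised without androgen, and lowered some genes that androgen had raised. At 12 h MTHFD1L rose by 1.36 ± 0.13, SLC7A2 by 1.35 ± 0.14, WNT10B by 1.33 ± 0.19, ECE2 by 1.27 ± 0.13 (0.85 on its other probe) and RRP9 by 1.14 ± 0.14 in cells with both treatments against R1881 alone. NDRG1 fell by 0.98 ± 0.18, SPDEF by 0.74 ± 0.12, the laminin gene LAMA1 by 1.07 ± 0.14, the secreted protein gene CRISPLD2 by 0.96 ± 0.17, and the androgen-induced methyltransferase gene GNMT by 0.74 ± 0.18. GNMT lost its call without R1881 replicate 2 or 3 or replicate 1 of both treatments (from −0.71 to −0.67). KLK2 fell by 0.79 ± 0.22 (adjusted p = 0.0313). Its call was lost in 6 of 16 alternatives, without the detection filter, in the fit to the 6 arrays alone, and without R1881 replicate 1 or 3 or replicate 1 or 2 of both treatments (from −0.86 to −0.59). KLK3, TMPRSS2 and FKBP5 had changes of −0.64 ± 0.21, −0.66 ± 0.25 and −0.14 ± 0.14, none past the test. With the replicate number as a block KLK3 and TMPRSS2 passed (adjusted p = 0.0199 and 0.00997), and KLK3 passed in 4 of 17 alternatives in all, among them no background correction (−0.55).

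Dox changed 92 genes in androgen-treated cells at 5 h, 90 up and 2 down, and 597 at 12 h, 407 up and 190 down. With array weights the counts were 174 and 1106, and the fit to the 6 arrays alone called 2 at 5 h. Without the replicate 1 array of both treatments the counts were 21 and 363. With 75th-percentile scaling the 12 h genes were 630 up and 120 down. Of the genes up with Dox at 12 h without androgen, 204 of 236 were also up with Dox in androgen-treated cells, where independent lists would share 10.5, and 33 of 53 were also down. These lists compare different arrays but share the variances of the joint fit, and 0 genes went opposite ways. At 5 h SOX8 rose by 1.29 ± 0.14, DCAF4, a ubiquitin ligase adaptor gene, by 1.17 ± 0.13, TWNK by 1.10 ± 0.13 and MNT, which encodes a partner that opposes MYC, by 1.03 ± 0.14. The 2 genes down at 5 h were PPP1R15A, a stress-response phosphatase subunit gene (fell by 0.74 ± 0.17), and ARID5B, a chromatin gene (fell by 0.48 ± 0.11). PPP1R15A lost its call in 10 of 16 alternatives, among them no background correction, and ARID5B in 8 of 17, among them 75th-percentile scaling. Leaving out any array but replicate 1 of both treatments ended the call of PPP1R15A (from −0.82 to −0.62), and any but replicate 3 of both that of ARID5B (from −0.52 to −0.40). TWNK and MNT lost theirs in the fit to the 6 arrays alone.

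Ribosome biogenesis genes had 10 of 32 members up at 5 h (19 adjusted over the list alone) and 23 at 12 h (26 adjusted over the list alone), with means of 0.416 and 0.579 and adjusted p of 9.74e-04 and 0.00135 with an estimated correlation. Of 29 androgen-induced genes, 8 fell at 12 h (14 adjusted over the list alone), with a mean of −0.416 and an adjusted p of 0.00135 with an estimated correlation. At 5 h that mean was −0.143 with 0 members past limma's adjusted test, and its adjusted p of 0.00109 became 0.155 with an estimated correlation. The nucleotide list had 10 of 24 members up at 12 h (14 up and 1 down adjusted over the list alone; mean 0.350, adjusted p = 0.0312 with an estimated correlation), with DHODH, a pyrimidine synthesis gene, at 0.88 ± 0.17 and CAD at 0.62 ± 0.15. CAD lost its call without R1881 replicate 1 or 2 or replicate 1 of both treatments (0.56 to 0.61). The mitochondrial list had 6 of 20 up (mean 0.296, adjusted p = 0.00135 with an estimated correlation), with PHB1, a mitochondrial scaffold gene, at 0.73 ± 0.13 and TIMM10 at 0.79 ± 0.11. The integrated stress response list had 9 of 17 up (mean 0.429, adjusted p = 0.011 with an estimated correlation), with PSAT1, a serine synthesis gene, at 0.71 ± 0.14, TRIB3 at 0.78 ± 0.12 and CEBPB at 0.74 ± 0.13. Growth-arrest genes had 4 of 13 down (mean −0.304, adjusted p = 0.011 with an estimated correlation), secretory pathway genes 1 of 13 down (mean −0.251, adjusted p = 0.00314 with an estimated correlation) and lineage transcription factors 3 of 7 down (mean −0.390, adjusted p = 0.00575 with an estimated correlation), among them HOXB13, which fell by 0.41 ± 0.09.

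Some list calls of this comparison at 12 h were lost with an estimated correlation. The unfolded protein response list had 4 of 17 members down (6 adjusted over the list alone) and a mean of −0.280, with an adjusted p of 2.63e-06, or 0.0518 with an estimated correlation. CRELD2, an endoplasmic reticulum stress gene, fell by 0.64 ± 0.13 and DNAJC3, a chaperone cofactor gene, by 0.56 ± 0.13, the latter not past the test in the fit to the 6 arrays alone and without R1881 replicate 1 or replicate 2 of both treatments (−0.42 each). G1/S and DNA replication genes had 4 of 25 up (13 adjusted over the list alone) and a mean of 0.370, with an adjusted p of 1.21e-07, or 0.158 with an estimated correlation, and UNG, a uracil repair gene, rose by 0.99 ± 0.12 on its brightest probe. Its other probes had changes of 0.61 (adjusted p = 0.0162) and 0.25 (adjusted p = 0.317), so the size for the gene is uncertain. Glycolysis genes had 4 of 19 up and a mean of 0.141, with an adjusted p of 0.0304, or 0.362 with an estimated correlation, and the regulator gene PFKFB3 rose by 0.70 ± 0.12, while its other probe had 0.47 and did not pass (adjusted p = 0.202). Translation factor genes had 1 of 14 up and a mean of 0.173, with an adjusted p of 0.0312, or 0.0518 with an estimated correlation. NCL, ODC1 and CDKN1A had changes of 0.47 ± 0.20, −0.20 ± 0.12 and −0.16 ± 0.21, none past the test, though NCL passed with the mean of its probes (adjusted p = 0.0154).

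Androgen still raised its targets in cells with Dox. At 12 h, against Dox alone, FKBP5 rose by 2.78 ± 0.14, TMPRSS2 by 2.98 ± 0.25, KLK3 by 2.42 ± 0.21 and NDRG1 by 2.01 ± 0.18, KLK2 was at least 6.66-fold and SGK1 at least 7.05-fold higher, and LRRN1, TMEM140 and ACKR3 fell by 1.57 ± 0.19, 1.97 ± 0.23 and 1.56 ± 0.26. In this comparison 93 genes changed at 5 h, 80 up and 13 down, and 471 at 12 h, 326 up and 145 down. The counts were 165 and 1030 with array weights, and 38 at 5 h in the fit to the 6 arrays alone. Without the replicate 2 array of both treatments, 52 genes changed at 5 h. At 12 h, 304 genes were up with androgen both without and with Dox, where independent lists would share 19.3, and 123 were down in both. Of 29 androgen-induced genes, 16 rose at 5 h (24 adjusted over the list alone) and 27 at 12 h (28 adjusted over the list alone), with means of 0.986 and 1.73. The unfolded protein response list had 5 of 17 up at 12 h (mean 0.386, adjusted p = 0.0282 with an estimated correlation) and the secretory list 3 of 13 (mean 0.301, adjusted p = 0.00132 with an estimated correlation).

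The interaction asked whether the androgen response differed with Dox. SLC35F2, a nucleoside transporter gene, was the 1 gene past the test at 12 h. It rose by 1.17 with R1881 alone and by 0.38 with R1881 on top of Dox, a difference of −0.80 ± 0.13 (adjusted p = 0.0305), while its other probe had −0.44 and did not pass. Its call was lost with 75th-percentile scaling, with the mean of its probes, in the fit to the 12 arrays alone and without any of 10 arrays in turn. Dox without androgen raised SLC35F2 by 0.56 at 12 h (limma adjusted p = 8.96e-04). In cells with R1881 its change with Dox was −0.23 and did not pass (adjusted p = 0.145). Much of the difference thus lay in cells without androgen. At 5 h limma called 0 genes for the interaction, with 126 at an unadjusted p under 0.05, and at 12 h 208 had an unadjusted p under 0.05. These were 1.38% and 2.28% of genes, below the share of 0.05 that chance gives where p-values are calibrated. The p-values of this contrast may thus run too large, so these counts do not show that the response was the same with Dox. FKBP5, KLK3 and TMPRSS2 had interaction values of −0.45 ± 0.20, 0.29 ± 0.30 and 0.18 ± 0.35 at 12 h, none past the test. Among lists, secretory pathway genes had a mean of −0.179 at 12 h with an adjusted p of 0.00872 with an estimated correlation. Androgen-induced genes had a mean of −0.196 and the unfolded protein response list −0.195, with adjusted p of 1.35e-04 and 5.58e-05, or 0.0948 and 0.163 with an estimated correlation. Hypoxia-inducible, G1/S and ribosome biogenesis genes had means of −0.293, 0.140 and 0.092, and their calls were lost too (adjusted p = 0.146, 0.584 and 0.425 with an estimated correlation). At 5 h androgen-induced genes had a mean of −0.056, not past the test, and ribosome biogenesis genes 0.093, with an adjusted p of 0.0195, or 0.986 with an estimated correlation.

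Genes called in the 5 h comparison gave a more direct reading of the 12 h response, though their calls used variances from all 24 arrays. Over the 157 genes that R1881 changed at 5 h, each taken in its 5 h direction, the mean response at 12 h was 1.32 ± 0.02 log2 units without Dox and 1.06 ± 0.02 with Dox, so 80.7% ± 1.9 of it was kept (fry adjusted p = 5.44e-05). Regrouping the arrays within each androgen arm gave as large a difference in 8 of 100 draws. Such draws carry the effect of Dox itself into the difference, so they do not show what chance would give. Of the 31 genes in this set that R1881 lowered, 26 had a positive interaction value at 12 h and 5 a negative one. Their mean change at 12 h was 0.040 with both treatments against R1881 alone (17 positive, 14 negative). With Dox against vehicle it was −0.218 (4 positive, 27 negative). For these 31 genes the difference thus lay mainly in cells without androgen. Among them, OSR2 and PCED1B were not above background at 12 h with R1881 or with both treatments. A further fall of such genes could not be seen, which may add to this pattern. Of the 126 genes in this set that R1881 raised, 107 had a negative interaction value at 12 h. With both treatments, 31 of the 126 were lower and 1 higher than with R1881 alone. In cells without androgen Dox lowered 6 and raised 2 of these 126 genes. In the other direction, over the 845 genes changed at 12 h, 88.1% ± 13 of the 5 h response was kept, which did not differ from the whole by the fry test (adjusted p = 0.284).

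**Figure D3:**
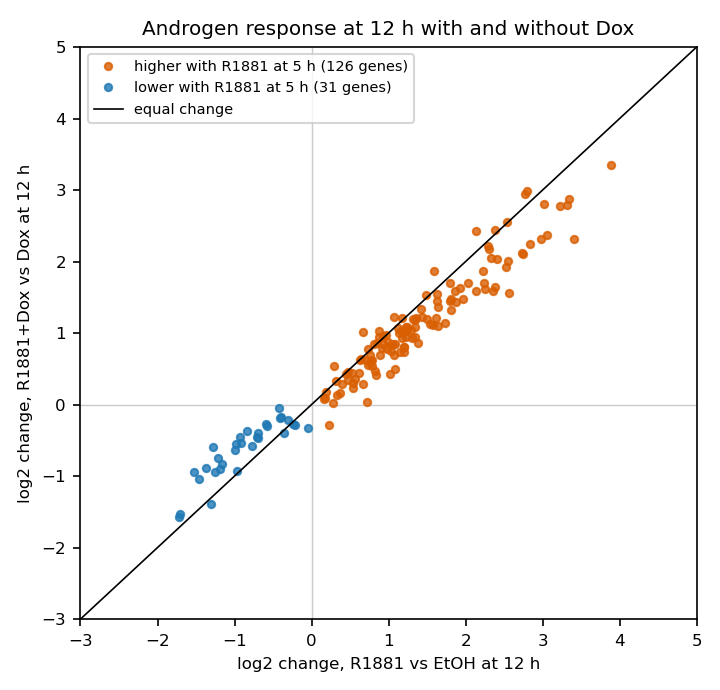
Log2 change with R1881 at 12 h in cells without Dox (horizontal axis) and with Dox (vertical axis) for the 157 genes that R1881 changed at 5 h, one point per gene, with the line of equal change. Of the 126 genes raised at 5 h, 107 lie below the line, and the mean response was 1.32 without and 1.06 with Dox.

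More genes passed for a difference between the times with R1881 than with Dox. Dox also changed fewer genes at 12 h (289 against 845), and no test compared the counts. The 12 h change with R1881 differed from the 5 h change for 119 genes, 91 with a more positive and 28 with a more negative change, and 62 passed in the fit to the 12 arrays alone. For Dox the corresponding count was 1, the transporter gene SLC1A3, which was above background with Dox at 12 h alone of these groups, with 348 genes at an unadjusted p under 0.05. That call was lost without background correction, with 75th-percentile scaling, with the authors' values, with a variance trend, with an array order block, in the fit to the 12 arrays alone and among genes detected on all 24 arrays. Vehicle at 12 h against vehicle at 5 h gave 0 genes by limma, with 401 at an unadjusted p under 0.05. Both 348 and 401 are fewer than a share of 0.05 of the 9113 genes, which chance gives where p-values are calibrated. The p-values may thus run too large here, so these counts do not show that no genes differ.

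With R1881 or Dox alone, the remaining lists did not pass the test at 12 h. With R1881 at 12 h, oxidative phosphorylation genes had a mean of −0.076, interferon-stimulated genes −0.155, immediate-early genes −0.043, MYC network partners 0.081 and G2/M genes −0.005, and with Dox at 12 h 0.005, −0.011, −0.007, 0.149 and −0.136, none past the test. Marker lists of other cell types had few measured members: 0 basal epithelial, 4 stromal, 2 leukocyte and 2 neuroendocrine genes. None of these lists passed with R1881 or Dox at 12 h, with means of −0.111, −0.282 and −0.101 for the latter 3 lists with R1881 and −0.051, −0.346 and 0.175 with Dox.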

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

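The tests of exchanged labels, of the probe's place, of array contrast, of endoplasmic reticulum stress, of members near background and of the drug itself were chosen only after the results they address were seen.

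A difference between the times was tested as a term of the model. With R1881, 119 genes changed differently at 12 h than at 5 h. Among genes named here, the change at 12 h was more positive than at 5 h for FKBP5 (1.89), NDRG1 (1.77), SPDEF (1.42), KLK2 (1.41), MANF (1.12), HSPA5 (1.08), CREB3L2 (0.91), SMS (0.74), ODC1 (0.70) and TMED9 (0.60), in log2 units. It was more negative for LRRN1 (−1.76), IL1RN (−1.70), ACKR3 (−1.60), PKIB (−1.46), TMEM140 (−1.40), LTN1 (−0.88) and CAMK2N1 (−0.86). IL1RN was above background on only 1 array with R1881 at 12 h, so the size of its difference is uncertain. SLC2A3, ORM1 and TRIM49D1, not above background with vehicle, passed as more positive (adjusted p = 1.30e-06, 0.00487 and 0.00687), and CCDC83, not above background with R1881 at 12 h, as more negative (adjusted p = 0.0337). The size of these 4 differences is not measured. Among lists, the difference was 0.880 for androgen-induced genes, 0.555 for the unfolded protein response, 0.437 for the secretory pathway, 0.214 for cholesterol and fatty acid synthesis and −0.638 for androgen-repressed genes, each past the list test with a preset and with an estimated correlation. With Dox, 1 gene differed between the times, SLC1A3 (adjusted p = 0.028), which was above background with Dox at 12 h but not with Dox at 5 h or with vehicle, so the size of the difference is not measured. Each time had its own vehicle arrays, so part of these differences comes from vehicle at 5 h and 12 h, between which 0 genes passed by limma (401 at an unadjusted p under 0.05).

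Probes without a single gene symbol belong to no gene count and carried signal of their own. Of 2846 such probes, 25 changed with R1881 at 5 h and 145 at 12 h, 3 and 30 with Dox, 6 and 44 with both treatments against R1881, and 12 and 86 with both against Dox. The steepest with R1881 at 12 h were ILMN_3279169 and ILMN_2335583, up by 3.45 ± 0.24 and 2.92 ± 0.22, and ILMN_2371458 and ILMN_1882519, which fell by 1.62 ± 0.23 and 1.55 ± 0.28. The sources used here pair them with no name.

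The MYC probe was lower with Dox at 12 h in cells without androgen, by −0.43 log2 units, although the construct should add MYC transcript. An exchange of the Dox and vehicle labels would turn the ribosome biogenesis list, which MYC raises, downward, and its mean was 0.487. A trend of normalization with brightness would move the 614 genes within 0.5 log2 units of the MYC probe alike, and their median change was −0.003 (SD 0.186), with 8 of them lower than MYC. It stays open whether the probe reads the endogenous transcript alone, which induced MYC may lower, since the probe's place relative to the construct is not known here. The change itself did not pass the test, but did with the replicate number as a block (adjusted p = 0.0183) and with array weights (−0.39, adjusted p = 0.0347).

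The androgen response at 12 h was smaller with Dox, at 80.7% of its size without Dox. If the arrays with both treatments had less contrast, the Dox response on them would shrink too. Over the 67 genes that Dox changed at 5 h, R1881-treated cells showed 111% ± 14 of the 12 h Dox response. That gave no sign of a loss, but with so wide an SE some loss of contrast is not excluded. If bright probes were compressed, the dimmer genes would keep their response, but the dimmer 79 of the 157 genes kept 75.6% ± 2.3 and the brighter 78 kept 86.2% ± 2.7. With 75th-percentile scaling the share was 84.8%, so part of the loss may come from normalization. Whether Dox itself or induced MYC lowers the response cannot be told apart, since no cells without the construct had Dox.

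The integrated stress response list was higher with Dox at 12 h, with a mean of 0.502. Endoplasmic reticulum stress would raise the unfolded protein response list as well, and that list had a mean of −0.085 (SE over members, widened for their correlation, 0.088). Noise near background would spare the brighter members, and the 13 members detected on all 24 arrays had a mean of 0.532 (SE widened likewise, 0.092). An effect of Dox on mitochondria, which the drug is known to impair, and an effect of MYC cannot be told apart, for want of Dox without the construct.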

How the results depend on the processing

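The counts, the shares kept, 8 list means and the values of named genes were computed again with 1 choice changed at a time, and none of them turned its direction past a threshold. Of 161 called values of named genes, 114 were called in every setting run and 47 lost their call in at least 1, most often on leaving out an array or in a fit to the compared groups alone. Of 127 values of named genes that were not called, 24 gained a call in at least 1 setting, most often with the replicate block or array weights. Without background correction 59 of the 161 called values were smaller by over 1.5 times, as were 58 with the authors' values, so the sizes of change depend on that correction.

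The single interaction gene at 12 h became 2 genes without background correction and with the authors' values, 0 with 75th-percentile scaling, with the mean of a gene's probes and in the fit to the compared groups alone, 4 with array weights and 2 with an array order block. The single gene of the time difference for Dox became 0 without background correction, with 75th-percentile scaling, with the authors' values, with detection on all 24 arrays, with an array order block, in the separate fit and with an eBayes trend, and 2 with the replicate block. The cause was not tested.

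With the replicate block the counts were 121 and 473 for Dox against vehicle at 5 h and 12 h, and at 12 h 828 for both treatments against R1881 and 630 for both against Dox, comparisons that the numbers pair. Where the arrays share only a number, they were 139 for both against R1881 and 145 for both against Dox at 5 h, and 227 for the time difference of R1881. In a fit to the compared groups alone, which has fewer arrays to estimate variances from, the counts were 43 for R1881, 0 for Dox, 2 for both against R1881 and 38 for both against Dox at 5 h, 156 for Dox at 12 h and 62 for the time difference of R1881. With array weights they were 101, 38, 174 and 165 at 5 h for R1881, Dox, both against R1881 and both against Dox, 737, 1106 and 1030 at 12 h for the latter 3, and 187 for the time difference of R1881. The cause was not tested. With a fold of at least 1.5, which removes genes by construction, 35 genes remained for Dox and 55 for both against R1881 at 5 h, and 494, 115, 250 and 299 at 12 h for R1881, Dox, both against R1881 and both against Dox.

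With an estimated correlation the androgen-induced list kept its mean of −0.143 for both against R1881 at 5 h and of −0.196 for the interaction at 12 h, but lost its call (adjusted p = 0.155 and 0.0948). This test allows for the correlation estimated between members, and the other 6 list results were unchanged.

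Leaving out 1 array at a time gave 102 to 146 genes for R1881 at 5 h, with 102 without vehicle replicate 3. For Dox at 5 h it gave 11 to 64, with 11 without Dox replicate 1, 33 without Dox replicate 2, 26 without vehicle replicate 3 and 42 without vehicle replicate 2. For both against R1881 at 5 h it gave 21 to 108, with 21 and 34 without replicates 1 and 2 of both treatments and 44 and 22 without R1881 replicates 1 and 3. For both against Dox at 5 h it gave 52 to 73, with 52 without replicate 2 of both treatments and 60 and 57 without Dox replicates 1 and 3. At 12 h the counts were 131 to 248 for Dox, with 176 and 131 without Dox replicates 1 and 2 and 144 and 134 without vehicle replicates 1 and 3. They were 363 to 462 for both against R1881, with 363 and 394 without replicates 1 and 2 of both treatments and 366 and 377 without R1881 replicates 1 and 3. The time difference of R1881 gave 75 to 137, with 76 and 75 without R1881 5 h replicates 1 and 3. The interaction at 12 h and the time difference of Dox gave 0 to 1, and each was 0 without any of 10 of the 12 arrays. The androgen-induced mean for both against R1881 at 5 h ran from −0.190 to −0.100, and lost its call without R1881 replicate 2 (adjusted p = 0.0505). The cause was not tested.

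The settings were run for 8 list means, of androgen-induced genes with R1881, for both against R1881 and for the interaction, and of ribosome biogenesis genes with Dox, each at both times. Apart from the losses given here, these kept their direction and whether they passed. The other lists were tested only with a preset and an estimated correlation and with fry, and many lost their call with an estimated correlation, as given beside those named in the report. The share of the androgen response kept at 12 h ran from 80.1% to 83.9% on leaving out arrays, was 84.8% with 75th-percentile scaling, and reached 86.7% over the genes that changed at least 2-fold at 5 h. A slide block was not run, since slides are not given. Signal over background limits the values of genes such as SGK1, ORM1 and SLC2A3, whose vehicle signal was not above background, to lower bounds. These bounds depend on the background correction.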

Other observations

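The array order block and the test on ribosome biogenesis genes with R1881 were chosen only after the results they address were seen.

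Within groups, arrays differed along 1 axis that held 31.6% of the residual variance. The sign of this axis alternated along the order of the arrays in the series for 12 of 12 arrays at 12 h and for 10 of 12 at 5 h. Its source is not given in the sources used here, and 1 candidate source is the processing of alternate arrays. With the array's odd or even place as a block within each time, 84 genes passed for Dox at 5 h and 308 at 12 h, 139 and 845 for R1881, and 98 and 669 for both treatments against R1881.

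The counts of genes were compared with other splits of the same arrays, and 3 arrays against 3 make 10 splits, too few for a share under 0.05. Each other split mixes the groups, so the real difference enters its spread, and its count is no measure of chance. At 12 h the real split gave 845 genes for R1881, 289 for Dox, 597 for both against R1881 and 471 for both against Dox, and the highest other split gave 0 in each of these 4 comparisons. At 5 h the real split gave 157 genes for R1881 and the highest other 3, and 92 for both against R1881 and the highest other 1. For Dox at 5 h the real split gave 67 and the highest other 69, and for both against Dox 93 and 159, so 2 of 10 splits gave as many in each. In the latter, the split with 159 genes put the 3 arrays on the negative side of the within-group axis against the 3 on its positive side, which points to a structure of the samples. Replicate numbers paired the arrays for Dox against vehicle at 5 h and 12 h and for both treatments against each alone at 12 h, where the other splits that part all 3 pairs called 0 genes, and the split with 69 genes parts 1 pair.

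For the interaction and the time differences, 100 splits were drawn that regroup arrays within the androgen arms or within the times. Such splits mix arrays that differ by treatment, so they carry effects of Dox or R1881 into the difference, and their shares neither exclude chance nor give its size. For the interaction at 12 h, 4 of 100 gave at least the real count of 1 gene, with 10 as the highest other. At 5 h the real count was 0, so all 100 gave as many, and the highest other gave 821 genes, on a split with 5 of 6 negative arrays of the within-group axis on 1 side. For the time difference of R1881, 11 of 100 splits gave at least 119 genes, with 683 as the highest other, and for that of Dox 14 of 100 gave at least 1, with 281 as the highest. For the time differences, the splits with the highest counts kept the real groups at 12 h while mixing those at 5 h, so the 12 h response was left in the difference.

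List means were compared with splits in the same way. For androgen-induced genes the real mean change and the highest other were 1.04 and 0.445 with R1881 at 5 h, 1.92 and 0.679 at 12 h, and in absolute size 0.416 and 0.168 for both against R1881 at 12 h. For ribosome biogenesis genes with Dox they were 0.323 and 0.180 at 5 h and 0.487 and 0.247 at 12 h. In each of these, 1 of 10 splits, the real one, was as large, too few splits for a share under 0.05. Each other split mixes the groups unevenly and so keeps part of the real effect, and the highest other value is no measure of chance. For androgen-induced genes and both against R1881 at 5 h, 2 of 10 were as large, with 0.143 and 0.152 in absolute size. For the interaction of this list, 58 of 100 splits were as large at 5 h and 45 of 100 at 12 h, with 0.056 against 0.246 and 0.196 against 0.516 as the highest other. For the share of the androgen response kept, the difference in response was 0.255 at 12 h, and 8 of 100 splits gave as large a difference, with 0.299 as the highest other. At 5 h it was 0.035, and 35 of 100 gave as large a difference, with 0.078 as the highest. In these splits Dox arrays trade places within each androgen arm, so the effect of Dox on the list enters the difference, and they decide nothing about chance.

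Less MYC transcript with R1881 might lower ribosome biogenesis genes, as the MYC probe fell at 12 h. Their mean change with R1881 was −0.115 at 5 h and −0.033 at 12 h. The SE over members at 12 h, widened for their correlation, was 0.067, so a fall by 0.1 log2 units at 12 h is not excluded, and the question stays open.

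Genes that lose more of their androgen response with Dox might be those that Dox lowers without androgen. Over the 157 genes that R1881 changed at 5 h, the Dox change at 5 h and the interaction at 12 h were compared. Both were signed by the androgen change, and their rank correlation across genes was −0.074. The median SE over all genes was 0.139 log2 units for the former and 0.197 for the latter. Noise of this size could hide such a link, so the question stays open. Genes are not independent replicates, so no p is given.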
